A study of Mus musculus with 4 samples.

How the data were processed

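Total RNA from mouse liver was sequenced in 4 libraries, 1 for each combination of genotype and feeding state, per the labels. The control libraries are labelled wild type with shNC. The targeted libraries are labelled with liver Cyb5b and shCyb5a, and no further detail of the allele, the hairpin vector, the sex or age of the mice or the lengths of fasting and refeeding is given in the sources used here. RNA was isolated with TRIzol, per the labels' protocols. Library preparation, strandedness, aligner, gene annotation and genome build are not given in the sources used here, so no genomic coordinates are printed and genes are named by the symbols and gene identifiers in the files.

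The data are 2 gene tables, targeted against control in the fasted state and in the refed state. Per the file headers, each table gives TPM (transcript share scaled to a fixed total) and FPKM for all 4 libraries, the log2 ratio of targeted over control made by the authors, and the authors' p-value for that ratio. The fasted table adds the authors' log2 ratio and p-value for refed over fasted control liver. TPM and FPKM were deposited with 2 decimals. The smallest absolute log2 ratio in either deposited table is 1 and the largest p-value is 2.43e-04 in the fasted and 1.46e-04 in the refed table, so the tables hold only genes past a threshold in their own state. A gene in neither table was not analysed here. For a gene in only 1 table, TPM in the other state is given in places without a counting interval and without a statement that it changed there. Each table has a shorter second sheet, with 14 and 33 genes, all of them in the first sheet with the same log2 ratio and TPM values. The second sheets were taken as selections made by the authors and not as independent evidence.

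How the authors made the log2 ratio and the p-value is not given in the sources used here, and both were examined from the values. The p-values match, within a relative tolerance of 0.001, a doubled tail of the Audic-Claverie distribution for whole reads of 2 single libraries in 682 of 685 fasted genes (99.6%) and in 249 of 250 refed genes (99.6%) whose p-value is above the numerical limit. The total reads implied are 1.01 times as many in the targeted as in the control library in each state. The log2 ratio equals, within 1e-06, the ratio of those whole reads without scaling in 84.5% of the fasted and 80.8% of the refed genes, and a gene at 0 reads enters the ratio as 0.01 reads. The p-values therefore compare the reads of 2 libraries, not the conditions, and are not used as tests here. On simulated reads the solving step recovered both read numbers in 618 of 618 fasted and 220 of 220 refed genes. It was given the true library ratio and the exact log2 ratio of whole reads above 0, which makes recovery easy. Estimating the library ratio, and log2 ratios that are not of whole reads, were not simulated. In 26 fasted and 21 refed genes the p-value is too small to solve.

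The comparisons below give TPM in each library and the ratio of TPM. For genes with recovered reads, the 95% Clopper-Pearson interval of the read ratio was moved to the TPM ratio. For genes whose p-value is too small to solve, the widest interval that p-value allows was used. These intervals cover counting error only and say nothing about the spread between mice, since reads without molecular identifiers are not independent molecules and each group has 1 library. A gene at 0 reads in 1 library is given as at least as many times different as its reads in the other library divided by a floor of 3 reads per library. Total reads per library are not in the tables. From the recovered reads and FPKM of genes with 1 annotated transcript in GENCODE M21, used for transcript lengths and for the sequence shared between 3 genes and others, the depth was estimated at about 13400000 reads for the targeted fasted, 13500000 for the control fasted, 13500000 for the targeted refed and 13500000 for the control refed library (medians over 82, 96, 30 and 21 genes). The lengths the authors used are not known, so these depths are approximate.

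The scale matters in the fasted state. TPM is 1.50 times FPKM in the targeted fasted library, 1.30 times in the control fasted, 1.25 times in the targeted refed and 1.23 times in the control refed library. The authors' log2 ratio minus the log2 ratio of TPM has a median of -0.18 in the fasted and -0.0042 in the refed table. Why the factor between TPM and FPKM differs between the libraries was not examined. A difference in the lengths of the transcripts read is therefore not excluded in the fasted pair.

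With 1 library per group, neither genotype within a feeding state nor its difference between states has residual degrees of freedom. A genotype effect averaged over both states would have 1, but was not tested, because the genes in the tables were selected on these same differences. edgeR and DESeq2 were not used because the tables hold no replicate counts. The tables hold no adjusted p-value, though thresholds on one had been allowed for. Before the data were examined, 26 lists of genes were fixed, covering sterol, lipid, bile acid, glucose, stress, xenobiotic, inflammatory, cell cycle, clock and sex-biased liver genes and markers of other cell types. For a list with at least 5 genes in a table, the percentile of its median log2 ratio was taken among 10000 random lists of the same size from the same table, matched on mean TPM in 5 bins. The percentile describes these libraries. The same matching was used to set the markers of other cell types against other genes lower in the fasted table. In a check on lists of random genes, 0 of 20 fasted lists fell outside percentiles 2.5 and 97.5, and of 20 refed lists 1 lay above and 1 below. Lists drawn only from higher genes lay above 97.5 in 20 of 20 cases in the fasted table but in 1 of 20 in the refed table, where most genes are higher.

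Genes are named by a rule fixed before the data were examined: Cyb5a and Cyb5b, the 10 highest and 10 lowest log2 ratios in each table among genes with a symbol of their own and at least 1 TPM in either library, up to 4 members per list with the largest absolute log2 ratio, and the 5 genes of each sign pattern with the largest summed ratio in both tables. Other genes that are named were chosen after their values were seen. Thresholds, low-value filters, pseudocounts of 1 and 0.1, unmatched random lists and gene matching were varied as planned, and the ratios of TPM and FPKM without a pseudocount were added after seeing the data. Members of gene families with near-identical copies, such as Mup, Cyp2, Cyp3a, Gsta, Gstm, Hba, Hbb, Serpina1 and Cphx, are uncertain, since how the authors assigned shared reads is not given in the sources used here. The percentile of a list that holds such copies counts them as separate genes. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.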

Results

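Liver transcripts were measured by RNA sequencing in control mice and in mice with both cytochrome b5 genes targeted, each in a fasted and in a refed state. Cytochromes b5 are small haem proteins that pass electrons to membrane-bound enzymes, among them enzymes of sterol and fatty acid synthesis, and the study's title concerns the removal of the C4 methyl groups of sterols in cholesterol synthesis. The 4 groups have 1 library each, with an estimated depth of about 13400000 to 13500000 reads. There are no replicates, so every difference below compares 2 libraries and has no replicate check. The ranges in parentheses after a fold are 95% counting intervals. The genes in the 2 deposited tables together hold 6.75% of all TPM in the targeted fasted library, 10.2% in the control fasted, 12.5% in the targeted refed and 16.5% in the control refed library.

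Both targeted genes had lower transcript levels in the libraries labelled as targeted. Cyb5a (gene ID 109672) stood at 1686 TPM in the control fasted and 207 TPM in the targeted fasted library, 8.13-fold lower (6.99 to 9.59). In the refed state it stood at 1274 and 166 TPM, 7.67-fold lower (6.70 to 8.85). Cyb5b (gene ID 66427) stood at 72.4 TPM in the control fasted and 27.4 TPM in the targeted fasted library, 2.64-fold lower (2.47 to 2.82). Its refed levels were 174 and 49.5 TPM, 3.51-fold lower (3.26 to 3.78). Transcript of both genes was still measured in both targeted libraries.

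The fasted comparison sets lower expression of both cytochromes b5 against control in liver without recent food. The listed genes for drug-metabolising P450 enzymes and most of those for bile acid synthesis and transport were higher in the targeted library, while the listed male-biased genes were lower, each with a median outside the range of random lists. The listed gluconeogenic genes and markers of other cell types were lower too, in a table where 69.7% of genes are lower. All 12 listed members of the microsomal P450 list were higher in the authors' deposited table, and their median log2 ratio of 1.73 lay above that of each of the 10000 matched random lists (percentile 100). Cyp3a11, a main drug-metabolising P450 of mouse liver, stood at 1152 TPM in the control and 5037 TPM in the targeted library, and Cyp3a59 at 12.6 and 82.5 TPM. Cyp2b9 rested on 3 control reads and 264 targeted reads and was 103-fold higher (34.7 to 501). Cyp2a4 was 19.9-fold higher (8.24 to 62.9) and Cyp2b10 7.91-fold higher (4.18 to 16.5). These P450 genes belong to families of similar copies, so their single values are uncertain. Of the 20 genes of the NRF2 and glutathione list, 3 were listed and all were also higher: Gstm3 by 5.36-fold (4.88 to 5.89), the quinone reductase Nqo1 by 2.45-fold (1.70 to 3.56) and the epoxide hydrolase Ephx1 by 2.39-fold (2.30 to 2.49).

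Of the bile acid list, 5 of 6 listed genes were higher in the fasted table, and the list's median lay at percentile 99.7. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 13.7 TPM in the control and 66.9 TPM in the targeted fasted library, 4.90-fold higher (4.49 to 5.35). The transporter genes Slco1a4 and Abcc3 were 3.49-fold (3.24 to 3.77) and 3.06-fold higher (2.89 to 3.25). Cyp7b1, an oxysterol hydroxylase, was the member listed lower, by 2.43-fold (2.25 to 2.62). Abcg8, which encodes one part of the sterol exporter of the canalicular membrane, was 2.49-fold higher (2.30 to 2.69), whereas Mylip, another target of the sterol receptor LXR, was 1.84-fold lower (1.55 to 2.20). The fixed list named other SREBP2 targets also holds Mylip, as its single gene in the fasted table. That entry is the same gene as in the LXR list and is not separate evidence on SREBP2. No gene of the cholesterol synthesis list is in the fasted table. Of the fatty acid and triglyceride synthesis list, Aacs and Elovl6 were listed, 2.68-fold (2.13 to 3.39) and 2.18-fold lower (2.01 to 2.36).

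Of the 20 genes of the gluconeogenesis and fasting response list, 4 are in the fasted table, and all 4 were lower in the targeted library. The list's enzyme genes Pck1, G6pc and Fbp1 are not in the table, so a fall of gluconeogenesis is not shown. Sik1 was 2.12-fold lower (1.92 to 2.34), Cebpb 2.04-fold (1.87 to 2.22), Igfbp1 1.90-fold (1.82 to 1.98) and Sds, a serine-degrading enzyme, 1.74-fold (1.65 to 1.83). Of the PPARa list, which covers fatty acid oxidation and ketogenesis, only the fatty acid transporter gene Cd36 was listed in the fasted table, 2.49-fold higher (2.27 to 2.73). Genes with higher expression in male liver were lower in all 8 listed cases, with a median at percentile 0.020. Among them, the major urinary protein genes Mup12, Mup7 and Mup1, which share near-identical copies, were 4.28-fold (3.88 to 4.73), 4.14-fold (3.77 to 4.57) and 4.14-fold lower (3.77 to 4.56), and Hsd3b5 was 3.31-fold lower (2.67 to 4.12). Mup11 and Mup15 are also among the 8, so the percentile counts copies that may share reads as separate genes. Outside the list, Mup9 was higher, on 358 control and 776 targeted reads, while Mup6, Mup8, Mup10, Mup14 and Mup16 were lower. All 4 listed female-biased genes were higher, namely Cyp2b9, Cyp2a4, Cyp2b10 and Abcd2. The first 3 of these are also members of the P450 list. Abcd2, a peroxisomal fatty acid transporter gene, was 2.69-fold higher (2.19 to 3.31).

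Markers of other cell types moved with the fasted comparison. Of the 138 genes on the 6 lists of endothelial, macrophage, lymphocyte, neutrophil, matrix and blood markers, 35 were in the fasted table and all 35 were lower in the targeted library, with a median 2.20-fold in TPM. Of these, 33 had their highest TPM of the 4 libraries in the control fasted library. Their choice as lower in the fasted targeted library favours this. The endothelium list had 13 of its 17 members in the table, among them Oit3, 2.72-fold lower (2.29 to 3.23), Emcn, 2.40-fold (1.43 to 4.17), Tie1, 2.33-fold (1.77 to 3.08), and Cdh5, 2.24-fold (1.85 to 2.71). All 7 listed macrophage and Kupffer cell genes were lower, including the scavenger receptor Marco, 2.95-fold (2.44 to 3.58), and Timd4, 2.20-fold (1.76 to 2.76). The 5 listed lymphocyte genes included the T cell genes Lck, 4.96-fold lower (2.50 to 10.9), and Cd3g, 4.48-fold lower (2.25 to 9.90), and their median lay at percentile 0.045. The macrophage, matrix and endothelium medians lay at percentiles 25.2, 17.1 and 27.5, within the range of random lists from a table in which most genes are lower. The 5 listed matrix and stellate cell genes were led by Mmp2 and Thbs1, each 2.68-fold lower (1.53 to 4.95 and 1.52 to 4.95). The 4 listed blood genes, among them haemoglobin genes Hba-a2 and Hbb-bs, were 2.11-fold (1.72 to 2.59) and 1.86-fold lower (1.64 to 2.11) for these members, and the neutrophil gene S100a9 was 2.98-fold lower (1.58 to 6.04).

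**Figure D1:**
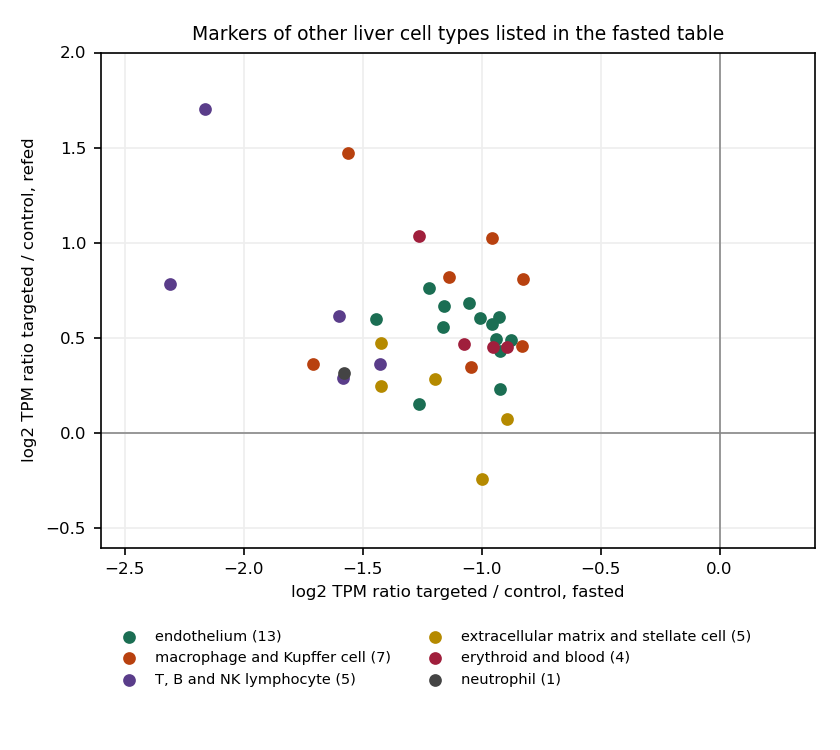
Each point is 1 of the 35 marker genes of other liver cell types in the fasted table, with the log2 ratio of TPM, targeted over control, in the fasted state on the x axis and in the refed state on the y axis. All 35 points lie left of 0 in the fasted state and 34 lie above 0 in the refed state.

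Across the whole fasted table, the authors' deposited table lists 722 genes, 219 higher and 503 lower (69.7% lower) in the targeted library. When the log2 ratio was recomputed from TPM with the same threshold, 214 genes were higher and 329 lower (60.6% lower), and with a pseudocount of 1 TPM as well 144 were higher and 128 lower (47.1% lower). From FPKM, 200 were higher and 494 lower (71.2% lower). Of these settings only the pseudocount of 1 TPM turned the split. A new scale can only remove genes here, since genes outside the table cannot enter, so these shares do not give the split of all genes on that scale. Besides the P450 genes above, the genes with the highest ratios included Mogat1, an enzyme of triglyceride synthesis, with 0 control and 13 targeted reads, at least 4.33-fold in reads. Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, was 8.39-fold higher (6.58 to 10.8), Npnt 9.86-fold (4.51 to 25.5), Lrtm1 6.40-fold (3.80 to 11.4), Megf9 6.10-fold (4.35 to 8.73) and Lmbrd2 5.91-fold (4.61 to 7.65). For Hist1h2br the scales disagree, with TPM of 0.07 and 9.67 but a log2 ratio of 3.65 in the authors' deposited table. Among the lowest, besides Cyb5a, Cphx1 was 24.7-fold lower (8.16 to 122) on 3 targeted reads, Serpina1e 6.70-fold (5.85 to 7.71), Rgs1 6.29-fold (4.25 to 9.63) and Gatad1 6.02-fold (4.85 to 7.53). Glipr1, Cib3 and Tspan32 each rested on 3 targeted reads, Gtse1 on 4 and Adam2 on 9.

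The refed comparison sets lower expression of both cytochromes b5 against control after food, when lipid synthesis genes are induced. The listed genes of cholesterol, fatty acid and triglyceride synthesis were lower in the targeted refed library, while the listed glutathione, P450 and sterol exporter genes were higher, in a table where 78.2% of genes are higher. All 7 listed genes of cholesterol synthesis were lower in the authors' deposited table. Idi1 stood at 134 TPM in the control and 47.2 TPM in the targeted library, 2.84-fold lower (2.68 to 3.02). Mvd was 2.79-fold lower (2.43 to 3.20), Lss, the lanosterol synthase, 2.41-fold (2.24 to 2.60) and Sqle, the squalene epoxidase, 2.23-fold (2.09 to 2.38). The list's median lay at percentile 6.56, and at 1.30 among random lists not matched on expression. None of these 7 genes is in the fasted table, and their median fasted log2 ratio was 0.24 by TPM but 0.04 by FPKM, so a higher fasted level rests on the scale.

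All 11 listed genes of fatty acid and triglyceride synthesis were also lower in the targeted refed library, with a median at percentile 0.860. Elovl6, a fatty acid elongase, stood at 167 TPM in the control and 26.6 TPM in the targeted library, 6.30-fold lower (5.59 to 7.12). Aacs was 3.55-fold lower (3.25 to 3.88), Fasn, the fatty acid synthase, 3.22-fold (3.01 to 3.45) and Pnpla3 2.72-fold (2.57 to 2.89). Acly and Lpin1, which stand both in this list and among the other SREBP2 targets, were 2.32-fold (2.21 to 2.43) and 2.09-fold lower (1.96 to 2.23). Within the control libraries, 17 of these 18 sterol and lipid genes were higher in the refed than in the fasted state, with a median of 8.89-fold over the 18, and within the targeted libraries 17 of 18 were higher with a median of 3.57-fold. Lpin1 was the exception in both genotypes. The refed over fasted ratio was smaller in the targeted libraries for all 18 genes, which their choice as lower in the refed targeted library nearly ensures.

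**Figure D2:**
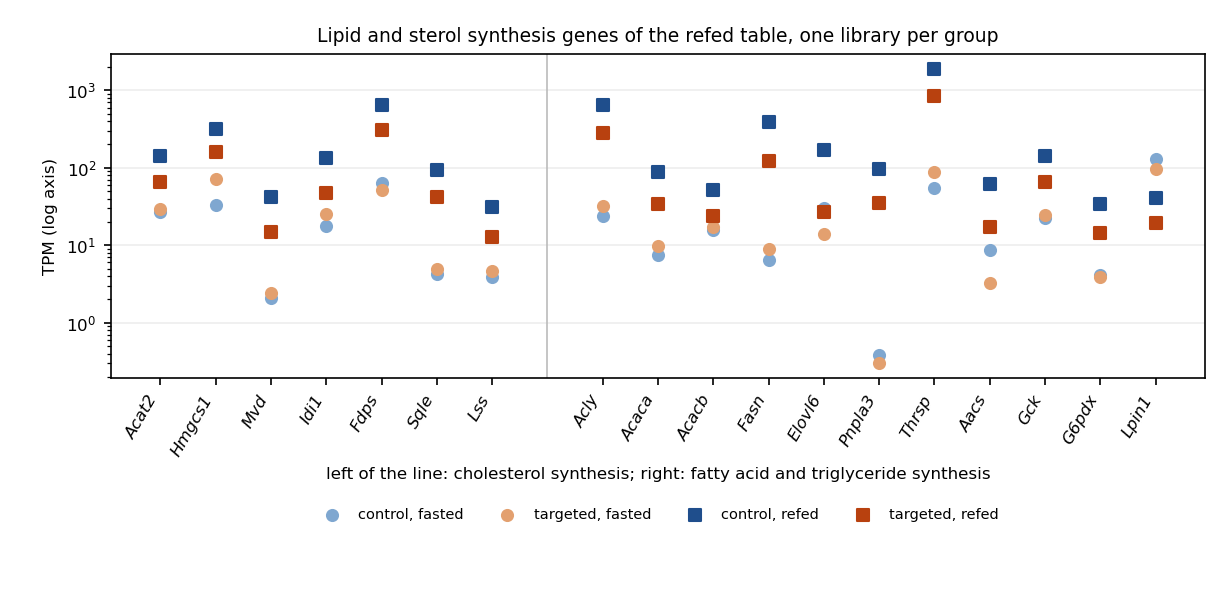
TPM on a log axis for the 7 cholesterol synthesis genes and the 11 fatty acid and triglyceride synthesis genes of the refed table, with 1 point per library and no error bars because each group has 1 library. The control refed library (dark blue squares) lies above the targeted refed library (dark orange squares) for all 18 genes.

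Of the 14 genes of the LXR list, 4 are in the refed table, and all 4 were higher in the targeted refed library. The list's Abca1, Abcg1 and Srebf1 are not in the table, in which 78.2% of genes are higher. Abcg5 and Abcg8, which together form the sterol exporter, were 2.84-fold (2.56 to 3.16) and 2.34-fold higher (2.11 to 2.59), Lpl, the lipoprotein lipase, was 2.37-fold higher (2.13 to 2.65), and Mylip stood at 1.75 TPM in the control and 3.50 TPM in the targeted library. All 3 listed bile acid genes were higher, namely Abcc3 by 3.49-fold (3.18 to 3.85), Slco1a4 by 2.87-fold (2.38 to 3.48) and Cyp7a1 by 2.17-fold (1.84 to 2.57). Of the PPARa list, Cyp4a31, Cyp4a14 and Acot1 were higher, by 3.86-fold (2.37 to 6.57), 3.66-fold (3.21 to 4.19) and 2.17-fold (1.54 to 3.09), and the hormone gene Fgf21 was 2.83-fold lower (1.60 to 5.24). Cyp4a14 fell on refeeding from 3674 to 9.84 TPM between the control libraries and from 4604 to 36.0 TPM between the targeted libraries. No gene of the gluconeogenesis list is in the refed table.

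Of the 20 genes of the NRF2 and glutathione list, 8 are in the refed table. All 8 were higher in the targeted refed library, with a median at percentile 99.9. Besides Ephx1 and Nqo1 they are Gsta and Gstm genes, and the list's Hmox1, Gclc, Gclm, Srxn1 and Txnrd1 are not in the table. Gstm3 was 6.16-fold higher (5.50 to 6.95), Gsta1 5.73-fold (3.58 to 9.59), Gsta2 3.68-fold (2.86 to 4.80) and Ephx1 3.30-fold (3.08 to 3.53). All 6 listed P450 genes were higher, with a median at percentile 99.0, among them Cyp2c55, 4.88-fold (3.61 to 6.72), Cyp3a59, 3.45-fold (2.95 to 4.05), Cyp3a11, 3.02-fold (2.84 to 3.22), and Cyp2a5, 2.94-fold (2.77 to 3.12). Among random lists not matched on expression, the percentiles of these 2 lists were 95.6 and 88.5, so their place among random lists depends on the matching. The glutathione transferase and P450 genes have similar copies and their single values are uncertain.

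**Figure D3:**
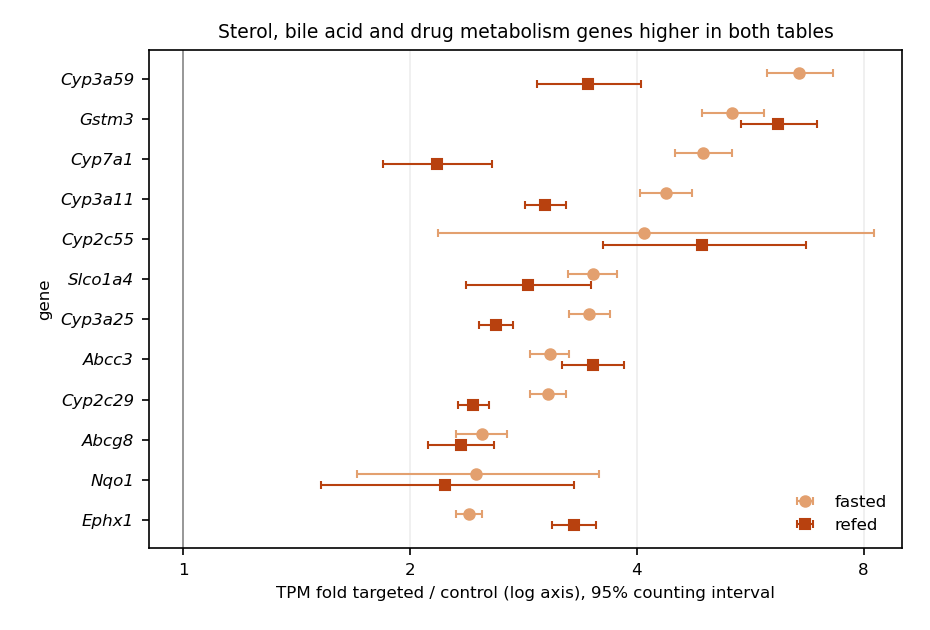
Fold of TPM, targeted over control, on a log axis for the 12 genes of the bile acid, LXR, glutathione and P450 lists that are higher in both deposited tables, with 95% counting intervals as bars. Fasted folds (light circles) run from 2.39 to 6.57 and refed folds (dark squares) from 2.17 to 6.16.

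Across the refed table, the authors' deposited table lists 284 genes, 222 higher and 62 lower (21.8% lower). With a pseudocount of 1 TPM, 81 were higher and 44 lower (35.2% lower). Among genes with a symbol of their own and at least 1 TPM in either library, the highest log2 ratios were those of Ccl21b and H2ac19, with 0 control reads and 16 and 13 targeted reads, at least 5.33-fold and 4.33-fold in reads. Cphx1 stood at 0.22 and 3.15 TPM, Xlr4a was 8.85-fold higher (2.15 to 78.1) on 2 control reads, Vtcn1 4.52-fold (1.75 to 14.9), and the mitotic genes Ckap2 and Trip13 were 6.08-fold (2.85 to 14.9) and 5.23-fold higher (2.42 to 12.9). Among the lowest, besides Cyb5a and Elovl6, Tmem254c had 52 control and 0 targeted reads, at least 17.3-fold lower. Moxd1 was 31.4-fold lower (8.31 to 265) on 2 targeted reads and Cphx2 12.0-fold (4.83 to 38.5) on 5. Gatad1 was 5.07-fold lower (3.97 to 6.54), Slc2a4, the insulin-regulated glucose transporter, 4.32-fold (2.59 to 7.54), Scara5 4.06-fold (3.36 to 4.93), Lmntd2 3.83-fold (2.46 to 6.19) and Zfp967 3.36-fold (2.42 to 4.76). For Zfp967 the scales disagree, with a log2 ratio of -2.35 in the authors' deposited table, outside that interval.

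The 2 feeding states were then compared. Of the bile acid, LXR, glutathione and P450 lists, 12 genes were higher in both tables, among them Cyp7a1, Slco1a4, Abcc3 and Abcg8, while Mylip was lower in the fasted and higher in the refed table. Cyp8b1 and Abcb11, higher in the fasted table, stood at 262 and 260 TPM and at 236 and 231 TPM in the control and targeted refed libraries. In all, 63 genes are in both tables, 26 higher in both, 10 lower in both, 24 lower in the fasted and higher in the refed table, and 3 higher in the fasted and lower in the refed table. When the log2 ratio was recomputed from TPM with the same threshold, 17 genes had opposite signs in place of 27. The number of genes tested is not in the tables, so the overlap of independent lists was not computed. By summed log2 ratio in the authors' deposited table, the first genes of the same sign were Evi2, 2210418O10Rik, Gm14296, Moxd1 and Cyb5a, an order that for genes at 0 reads, such as Evi2, comes from 0 entered as 0.01. Evi2 had 0 control reads and 13 and 18 targeted reads in the fasted and refed state. Gm14296 stood at 6.61 and 12.6 TPM in the control fasted and refed libraries and at 0 and 0.64 TPM in the targeted ones. 2210418O10Rik had 0 reads in the control refed and 385 in the targeted refed library, but 89 and 361 in the fasted pair.

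The markers of other cell types that were lower in the fasted targeted library were higher in the refed targeted library in 34 of 35 cases, with a median 1.41-fold in TPM. Of the 465 other genes lower in the fasted table, which include further endothelial and immune genes such as Cd93 and Cd74, 77.0% were higher in the refed pair. The exception was Tagln, which stood at 15.6 and 13.3 TPM. In the refed table itself, 4 markers were listed and all 4 were higher, namely Marco by 2.78-fold (2.21 to 3.52), Clec7a by 2.27-fold (1.83 to 2.83), the plasma cell gene Jchain by 2.53-fold (1.89 to 3.41) and the endothelial gene Lyve1 by 2.57-fold (1.94 to 3.45). Between the control libraries the median marker stood 2.48-fold higher in the fasted than in the refed state, and between the targeted libraries the fasted level was 0.714 of the refed level. Choosing the 35 markers as lower in the fasted targeted library favours both values. By the same sum, the first genes of opposite sign, apart from Gm2007, Cphx1 and Cphx2, which are predicted or have a near-identical copy, were Ppp1r3g and Slc15a2. Ppp1r3g, which encodes a glycogen-targeting phosphatase subunit, was 2.54-fold lower (2.32 to 2.78) in the fasted and 4.43-fold higher (1.92 to 11.9) in the refed targeted library. Slc15a2, a peptide transporter gene, was 3.33-fold lower (2.63 to 4.25) and 2.79-fold higher (1.83 to 4.38). Of the 500 genes lower in the fasted table with a TPM above 0 in both refed libraries, 20.6% were also lower in the refed pair, and of the 213 higher genes 68.1% were also higher. Of the 215 genes higher in the refed table, 57.7% were also higher in the fasted pair by TPM but 47.4% by FPKM, so that share depends on the scale. The difference between feeding states has no residual degrees of freedom with 1 library per group and was not tested.

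The second sheet of the fasted table holds 14 genes, 9 higher and 5 lower, and the second sheet for the refed state holds 33 genes, 18 higher and 15 lower. They include both targeted genes, Cyp7a1, Abcg8 and Elovl6 in both states. As these sheets were selected on the same libraries, their directions are not independent evidence.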

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

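The tests of the other cell types and of the scale were chosen after the results were seen, and the test of the feeding response was written down before its result. Values for a group or gene below are changes of the targeted over control ratio from the fasted to the refed state, for those that lay on opposite sides in the 2 states, the groups by TPM and by FPKM alike. They were not tested. Each group was picked by passing the threshold in the state of its table, which by itself favours a change between the states.

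The markers of other cell types are weighed first. Their median log2 ratio of TPM moved from the fasted to the refed state by 1.44 for the 5 matrix and stellate cell genes of the fasted table, by 1.85 for its 7 macrophage genes, by 2.21 for its 5 lymphocyte genes and by 1.58 for its 13 endothelial genes. The choice of the deposited ratio over TPM is argued against as the whole cause, since the deposited ratio differs from that of TPM by a median of -0.18 over the 35 markers. A shift common to both scales would not show in that difference and was not tested. A loss of these cells in both states was not seen, with 2.86% of the markers lower in the refed targeted library. That cannot decide against such a loss, because the refed pair has 1 library per genotype and the share of these tissues in each piece is not known. Against matched sets of other genes lower in the fasted table the markers lay at percentile 87.5, but those genes include at least 9 unlisted endothelial and immune genes, so a change shared by all lower genes and a change in these cells cannot be told apart. Nor can an unequal share of these tissues in the fasted pieces of liver and an effect of genotype that depends on feeding. The share could be smaller in the targeted or larger in the control fasted piece. Of the 35 markers, 33 had their highest TPM in the control fasted library, which their choice favours. The comparison of the 6 cell types, whose medians span 0.59, is void. Only 25.4% of the fixed markers are in the table, each picked by passing the threshold.

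A second pattern is the lower expression of lipid and sterol synthesis genes in the refed targeted library, of which the 11 fatty acid and triglyceride genes had fasted medians of 0.13 by TPM and -0.07 by FPKM, so no clear side. For the 7 cholesterol synthesis genes of the refed table the log2 ratio changed from the fasted to the refed state by -1.40, from fasted medians of 0.24 by TPM and 0.04 by FPKM. The choice of the deposited ratio over TPM is argued against as the whole cause, since the deposited ratio differs from that of TPM by a median of -0.0056 over the 18 genes. Here too a shift common to both scales would not show and was not tested. Among other genes of the fasted table that fall at least 4-fold on refeeding, the median refed log2 ratio of targeted over control was 0.66 for 89 genes chosen in the control libraries and 0.38 for 48 chosen in the targeted libraries. The response counts as smaller only with both at 0.5 or above and as full only with both below 0.25, so a smaller feeding response of the whole liver in this animal or pool and an effect of the genotype on these pathways cannot be told apart.

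Other results of the same kind are given as values. The 5 acute phase genes of the refed table moved by 1.59 between the states, from a median log2 ratio of TPM of -0.53 in the fasted to 1.06 in the refed state. The 13 cell cycle genes of that table moved by 2.09, from -0.52 to 1.57, alongside the markers of other cell types. In the authors' deposited table, 27 genes have opposite signs in the 2 states. Refed minus fasted, the authors' deposited table gives a log2 difference of -23.16 for Gm2007, 8.15 for Cphx1, -5.19 for Cphx2, 3.73 for Ppp1r3g and 3.70 for Slc15a2. The value for Gm2007 comes from 0 reads entered as 0.01 in each state and has no meaning as a size.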

How the results depend on the processing

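The TPM and FPKM ratios without a pseudocount, and the FPKM and low-value settings for the comparison of states, were chosen after seeing the data. The thresholds of an absolute log2 ratio of 1 and of a p-value of 0.01 or 0.05 removed no gene, because the tables hold only genes past them, so they say nothing about stability. At an absolute log2 ratio of 2, the fasted table keeps 38 higher and 61 lower genes (61.6% lower), and in the refed state 45 higher and 16 lower genes remain. With log2 from TPM and a pseudocount of 1 these were 144 and 128 in the fasted table, which turns the split to 47.1% lower, and 81 and 44 in the refed table (35.2% lower). A pseudocount of 0.1 gave 307 lower fasted genes (59.0% lower) and no pseudocount 329 (60.6% lower). By construction a new scale can only remove genes here, as genes outside the tables cannot enter. With no pseudocount 17 genes had opposite signs in both tables. Leaving out genes that stand in more than 1 list took Cyp7b1 from the bile acid list, so 0% of its fasted members were lower. Against unmatched random lists the refed percentile was 1.30 for cholesterol synthesis, 95.6 for the glutathione list and 88.5 for P450 genes, and for these the cause was not tested. By FPKM, 47.4% of the refed higher genes and 61.4% of the refed lower genes lay on the same side in the fasted pair, and the median refed over fasted fold in the targeted libraries turned to 1.07 for the glutathione and 1.17 for the acute phase genes of the refed table. The cause of these turns is the scale itself, as the same genes enter. All 461 recomputed log2 ratios of named genes kept their sign, which their choice past an absolute log2 ratio of 1 nearly ensures. Under a pseudocount of 1 TPM, 82 values lay outside the counting interval of the deposited ratio or had none, and 75 lay inside. For a pseudocount of 0.1 these numbers were 33 and 124, and for no pseudocount 23 and 124. Replicate counts are absent, so edgeR, DESeq2 and fits with replicates left out were not run. The labels give no replicate numbers by which libraries could be paired. Pairing the genotypes by feeding state, with 1 degree of freedom, was not done, and no adjusted p-value could be varied. Depth limits genes with few reads, such as those on 2 or 3 reads in the lower library, whose intervals span up to an order of magnitude or more.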

Other observations

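The tests of gene copies below were chosen after the folds were seen, but the bounds of the sequence test were set before it was run. Further fixed lists had members in the tables, with medians inside the range of random lists or too few members to place. All 13 listed cell cycle and mitosis genes were higher in the refed targeted library, with a median at percentile 77.3, among them Hmmr, 4.68-fold (2.25 to 10.9), Ccnb2, 4.08-fold (2.01 to 9.14), and Cdc20, 3.49-fold (1.93 to 6.67), while Tpx2 was 2.97-fold higher on 13 control and 45 targeted reads. Their levels were low, at 0.89 to 2.65 TPM for these 4 in the targeted refed library. In the fasted table Top2a and Mki67 were listed, 2.35-fold (1.45 to 3.92) and 1.85-fold lower (1.29 to 2.68), next to the lower markers of other cell types. Clock genes were listed in both states. Dbp and Ciart were 2.98-fold (2.28 to 3.93) and 2.84-fold lower (2.12 to 3.84) and Npas2 3.83-fold higher (1.91 to 8.33) in the fasted targeted library, and Nr1d2 and Nr1d1 were 4.45-fold (3.75 to 5.30) and 3.79-fold higher (3.07 to 4.72) in the refed one. The hour of tissue collection is not given in the sources used here.

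All 5 listed acute phase genes were higher in the refed targeted library, with a median at percentile 47.4, among them Orm2, 2.16-fold (1.84 to 2.55), Saa3, 2.14-fold (1.73 to 2.66), Saa2, 2.07-fold (1.89 to 2.26), and Hamp, the gene of the iron hormone hepcidin, 1.96-fold (1.83 to 2.11). In the fasted state Hamp2 and Orm3 were 4.88-fold (3.86 to 6.23) and 3.22-fold higher (2.02 to 5.28) and Saa3 2.39-fold lower (1.85 to 3.12). The interferon response genes Oas2, Gbp4 and Oasl2 were 2.32-fold (1.80 to 3.02), 1.83-fold (1.49 to 2.25) and 1.76-fold lower (1.35 to 2.31) in the fasted state, with the markers of other cell types, and Rsad2 was 2.18-fold higher (1.85 to 2.58) in the refed state. Of the stress response list, Sesn2 was 2.32-fold higher (1.80 to 3.03) and Gdf15 3.79-fold lower (2.43 to 6.11) in the fasted state, and none was listed in the refed table. Of the adipose markers, Fabp4 and Plin4 were 2.27-fold (1.79 to 2.91) and 2.25-fold lower (2.03 to 2.50) in the fasted and Plin4 3.19-fold lower (1.93 to 5.50) in the refed state. Serpina1e was the single listed gene of the secreted hepatocyte proteins in the fasted table, and none was in the refed table. Of the sex-biased lists, the refed table holds the male-biased Ces2b, 2.94-fold lower (2.12 to 4.12), and the female-biased Abcd2, 2.64-fold higher (1.85 to 3.83). By TPM, all 8 male-biased genes of the fasted table were also lower in the refed pair, with a median log2 ratio of -0.60. Of its 4 female-biased genes, the 3 with a TPM above 0 in both refed libraries were higher there. Among these genes of the fasted table, only Abcd2 is in the refed table. No biliary and no pancreas or gut marker is in either table, and no neutrophil, matrix or blood marker is in the refed table. The metallothionein genes Mt1 and Mt2, named after their values were seen, were 2.41-fold (2.25 to 2.59) and 2.13-fold lower (1.98 to 2.28) in the fasted state, and Mt2 was 2.35-fold higher (1.64 to 3.40) in the refed state.

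Drug metabolism and glutathione genes in both tables were higher in both, and reads moved between near-identical gene copies might raise single members of such families. Nqo1, Ephx1 and Abcc3 were examined by the share of their 31-base stretches that transcripts of other genes hold too, with at most 1% for each set as the bound against moved reads and 10% as the bound for them. Ephx1 shared 3.25%, between the bounds, so for the 3 genes together moved reads and a gain cannot be told apart, while for Nqo1 and Abcc3 alone, a split made after seeing this, moved reads are argued against at 0% shared. For the Cyp2, Cyp3a, Gsta and Gstm families, the summed TPM of the 18 members in the tables was 2.94-fold higher in the fasted and 2.57-fold higher in the refed targeted library, but with 46.2% of the 39 members on the fixed lists in the tables, a loss in copies outside them and a gain cannot be told apart. An effect of the genotype on these genes remains an untested hypothesis, as does a difference between single animals.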
